A study of Mus musculus with 5 samples.

How the data were processed

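The series holds 5 single-cell RNA samples of mouse T cells, made with 10x Genomics 3′ gene expression chemistry with hashtag antibodies, per the labels' protocols. In 4 samples, CD90.2 donor T cells were sorted from the eyes of 4 CD90.1 congenic B10.RIII recipients 1 week after injection into the vitreous. The fifth sample was taken as uninjected naive T cells of donor mice, from its title, its donor genotype and the protocol, although its title, source and tissue labels also say Eye. Per the labels the donors lack Tcra, carry R161H (a transgenic T cell receptor that recognises a retinal protein) and carry a green fluorescent reporter of Foxp3. The labels give an age of 6 to 10 weeks for all samples. Samples were grouped by their titles into eye (4 mice) and naive (1 sample). Each eye sample is 1 mouse, so p-values of the eye comparison measure the spread between mice, with the lone naive sample assumed to vary alike. In the comparisons of gated cells within the eye, they measure how the difference within a mouse varies over the mice. The number of donor mice is not given, so spread between donors was not measured.

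The authors deposited UMI counts per gene and cell, one matrix per sample, already limited to cell-containing barcodes and split by hashtag. Cell Ranger 7.1.0, Seurat 4.3.0 and the mm10 build are named per the submitters' processing notes; the gene annotation version and any doublet removal are not given in the sources used here. The matrices hold whole-number counts of 32285 genes and, after them, hashtag counts, which were kept out of library sizes and tests. Each eye sample's own hashtag took 95.1% to 99.1% of its tag UMIs, and the naive sample's own tag took 86.2%. The 4 eye samples shared 1 hashtagged capture and the naive sample came from another, as the deposited file sets are named, so the capture and the group cannot be told apart in any comparison of eye with naive. Coordinates are from GENCODE M21, on the GRCm38 (mm10) assembly.

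Of 9414 barcodes, cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. The doublet caller Scrublet, as run in scanpy, was applied per capture. It marked 37 naive cells (2.33%) but 1 of 7540 eye cells (0.0133%), so it appears not to have worked on the eye capture. Whether doublets were removed before deposit is not given, and doublets within the eye samples remain a limit. Settings without any doublet removal, without the 5% of T cells with the most UMIs per sample and without the 5% of cells with the highest doublet scores were also run. In the eye samples the first differs from the main setting by 1 cell, and the last uses scores of the same Scrublet run. Neither can stand in for doublet removal there, and leaving out the cells with the most UMIs does so only roughly. Cells were log-normalised to 10000 and clustered on 2000 variable genes without receptor variable genes, with 30 principal components, 20 neighbours and Leiden resolution 0.8, which gave 12 clusters. A cluster was called "X-like" from marker lists where at least 3 markers of 1 class were up. Clusters with tied classes, or with few UMIs for their sample and no such marker among their leading genes, stayed unnamed. T cells were those with a UMI of Cd3d, Cd3e, Cd3g, Trac, Trbc1 or Trbc2 outside the photoreceptor-like and macrophage-like clusters, which left 1320, 1777, 2206 and 2093 eye T cells and 1546 naive T cells. T-cell UMIs summed to 17638204, 18028046, 37087830 and 20124856 in eye mice 1 to 4 and to 6793151 in the naive sample, with a median of 8781 to 13990 UMIs per eye cell against 4206 per naive cell.

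Counts were summed per sample and tested with edgeR's quasi-likelihood test after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment; cells were never treated as replicates. In the eye comparison a gene was called at an adjusted p under 0.05 and a fold of at least 2, in the gates at an adjusted p under 0.05. The Foxp3 gate set T cells of the eye with 1 or more Foxp3 UMI against those with 0. The FR4 CD73 gate set eye T cells with 0 Foxp3 UMI and at least 1 UMI of both Izumo1r (FR4) and Nt5e (CD73) against those with 0 of both. The gate genes themselves and Foxp3 were left out of the gate tests. Both gates' sums come from the same mouse, so the mouse was a block, and each of the 8 sums held at least 20 cells. Residual degrees of freedom were 3 in each fit, and the common biological coefficient of variation was 0.191 for the eye comparison, 0.0870 for the Foxp3 gate and 0.0985 for the FR4 CD73 gate.

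Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, leaving out 59, 66, 54 and 80 shallower eye cells and 45 naive cells. The eye mean and SD cover 4 mice, the naive share has an exact 95% binomial interval for counting error only, and a count of 0 allows a share of 3 counts of the total. The two-sided exact permutation test of 4 mice against 1 sample cannot go below 0.2. Free RNA was judged from 32 photoreceptor-like cells of the eyes past that depth, which should lack T cell genes. For Foxp3, Il10 and Ikzf2 it was also judged from eye T cell clusters with low shares, a step added after their values were seen.

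The 33 gene lists were tested with camera at its preset correlation of 0.01, on the same sums and design, with adjustment over the lists. They cover regulatory T cells, anergy, co-inhibition and exhaustion, naive cells and quiescence, activation, Th1, Th2, Th17, follicular helper and type 1 regulatory cells, cytotoxicity, S phase, G2 and M phase, interferon, TGF-beta and retinoic acid responses, tissue residency, chemokine receptors and integrins, glycolysis, oxidative phosphorylation, cholesterol synthesis, dissociation stress and apoptosis. Further lists hold markers of other cells: macrophages, dendritic cells, B cells, neutrophils, photoreceptors, Mueller glia, lens, pigment epithelium, endothelium and platelets. Fewer than 3 members were tested of the neutrophil, pigment epithelium, endothelium and platelet lists in every comparison, of the Mueller glia and lens lists in the Foxp3 gate, and of all lists of other cells in the FR4 CD73 gate, so these have no result. Several genes stand in more than 1 list (Ctla4, Lag3, Il10 and Prdm1 among them), so lists are not independent. No camera call in any comparison held with an estimated correlation, and those adjusted p-values stand beside each call. That setting also rests on the 3 residual degrees of freedom, so few lists could pass it whatever their correlation. The Th1 list in the eye comparison had an estimated correlation of −0.0095, below the preset. Its unadjusted camera p still went from 6.9e-09 to 0.0082. These adjusted p-values therefore do not show that correlation between genes undoes a call.

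The sample groups, tests, cell filters, markers, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, per comparison, the 12 largest rises and falls among called genes with an average log2 CPM of at least 5, up to 4 members per list with the lowest adjusted p, 16 key genes and the genes that describe clusters. The text names part of those genes, and results of a few genes are not reported here. Where 5 or fewer members of a list were called in a direction, all are named apart from those not reported, and those outside the rule were chosen after their values were seen. Where the naive sample had 0 counts of a gene, its fold is a lower bound against 3 counts over that sample; with 1 to 3 counts, the ratio of the mean CPM is given with an exact Poisson interval of the naive count. The fitted log2 folds of genes with 0 counts are no bounds and are not printed, apart from 1 for Foxp3 in cells chosen to lack it. Histone genes, the Ifi200, Ifit and Gbp families, Ly6a, Serpinb6b and Tcrg-C1 with Tcrg-C2 have near-identical copies that 3′ counting could split, so their values are uncertain.

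On simulated counts with 200 changed genes, edgeR recovered 20.6% of genes changed 2-fold and 73.5% of those changed 4-fold in the eye comparison, run on 14269 genes, with 3 of 14074 unchanged genes called. In the Foxp3 gate (11994 genes) it recovered 89% and 99.0%, with 17 of 11798 unchanged genes called. In the FR4 CD73 gate (10065 genes) it recovered 78.6% and 100%, with 20 of 9870. These 20 false calls stood beside 77 and 97 correct ones, and the 17 of the Foxp3 gate beside 89 and 95. In both gates false calls were thus a larger share of the calls than the 0.05 aimed at. DESeq2 made 0 false calls in the FR4 CD73 gate, where it recovered 65.3% and 95.9%. It made 10 in the Foxp3 gate and 23 in the eye comparison. No simulated gene was called in the wrong direction. In the simulated eye comparison the naive sample varied like the eye samples and no capture effect was added. Only 200 genes changed there, against 4564 called in the data. Its recovery and false calls therefore need not hold for the real eye comparison.

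Alternatives were DESeq2, limma-voom for the eye comparison, other scalings, no low-count filter, other cell filters and doublet settings and all cells past the filters. Further ones were no cycling cells, sums at equal depth, gates set on thinned cells, cells matched on UMIs and other gates. No mouse block, each mouse left out, other thinning depths, other clusterings, fry and an estimated correlation were also run. The thinned gates chose cells at 2000 UMIs but summed their full counts, so those sums were not at equal depth. Added after seeing the data were settings without the low-UMI cluster, the highest-UMI cells, the highest doublet scores or the regulatory T-like cluster, the last also with matched cells or without the cycling cluster rich in Foxp3, and settings limited to cells with Y-linked or with Xist UMIs. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.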

Results

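Single-cell RNA profiles were collected from CD4 T cells with a receptor for a retinal protein. Some of these were naive cells of donor mice, and others were recovered after transfer into the eye, where immune responses are restrained (ocular immune privilege). The naive cells were a separate sample, not the transferred cells at an earlier time. Donor cells recovered from the eyes of 4 recipient mice 1 week after injection into the vitreous gave 7805 barcodes, and naive T cells that the protocol describes as freshly sorted from donor mice gave 1609, although their tissue label also reads Eye. After cell filters, 1320, 1777, 2206 and 2093 eye T cells and 1546 naive T cells were analysed. Median genes per cell were 3440, 3082, 3842 and 3033 in the eye samples and 1902 in the naive sample. The title of the series names regulatory and anergic signatures, anergy being a state in which T cells do not respond to their antigen. Both were addressed by 3 comparisons: eye against naive cells, eye cells with against without Foxp3 transcripts, and, among Foxp3-negative eye cells, those with against without transcripts of both anergy markers FR4 and CD73.

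The key genes are protein-coding and were placed on the GRCm38 assembly. Foxp3 (ENSMUSG00000039521) lies on chromosome X, 7573644 to 7595245, plus strand, and Il10 (ENSMUSG00000016529) on chromosome 1, 131019845 to 131024974, plus strand. Izumo1r (ENSMUSG00000031933), which encodes FR4, lies on chromosome 9, 14885814 to 14903949, minus strand. Nt5e (ENSMUSG00000032420), which encodes CD73, lies on chromosome 9, 88327197 to 88372092, plus strand. On chromosome 1 also lie Ctla4 (60887000 to 60915832, plus strand), Ikzf2 (69531214 to 69687245, minus strand), Pdcd1 (94038305 to 94052553, minus strand) and Il17a (20730905 to 20734496, plus strand). Lag3 lies on chromosome 6 (124904361 to 124911705, minus strand), Il2ra on chromosome 2 (11642807 to 11693193, plus strand), Tigit on chromosome 16 (43648867 to 43664146, minus strand) and Ifng on chromosome 10 (118441046 to 118445892, plus strand). Ccr7 lies on chromosome 11 (99144196 to 99155077, minus strand), Cd44 on chromosome 2 (102811141 to 102901665, minus strand) and Mki67 on chromosome 7 (135689784 to 135716361, minus strand). Sequencing from the 3′ end counts each gene as a whole, so exons and transcript forms were not compared.

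Which cell states the transferred cells took up was described by clustering. A regulatory T-like cluster with markers Foxp3, Il2ra, Ctla4, Tnfrsf18, Tnfrsf4, Lrrc32 and Itgae held 24.8% ± 11.2 of eye cells (SD, n = 4 mice). It was led by Il10, a cytokine that dampens immune responses, with Ccr2, Ccl5, Gzmb and Frmd5. Among its 10 leading genes 2 were in the fixed cluster markers of Th1 cells (Ccl5 and Gzmb) and 1 in those of regulatory cells (Foxp3). In the gene lists tested below, Ccl4 and Ccl5 stood under Th1, Foxp3 and Il10 under regulatory, and Gzmb under cytotoxic genes. A Th17-like cluster with markers that included Il17a, Il1r1, Tmem176a and Tmem176b held 24.4% ± 4.91. Among its 10 leading genes 2 were gamma-delta T cell markers, Tcrg-C1 and Tcrg-C2, 1 was a Th17 marker, Il17a, and 1 a Th1 marker, Cxcr6. An unnamed cluster led by Xcl1 and Tnfsf8 held 17.5% ± 3.42; in it anergy markers (Egr2, Egr3, Nr4a3, Tox) tied with follicular helper markers (Cxcr5, Bcl6, Tox2, Sh2d1a). Cycling T-like cells formed 2 clusters with 15.9% ± 9.41 together, and naive T-like cells with Ccr7, Tcf7, Klf2, S1pr1 and Igfbp4 held 7.33% ± 3.69. The latter name rests on those 5 markers only. In thinned cells of that cluster Ctla4 was found in 86.8% ± 2.15, Nt5e in 47.1% ± 1.33 and Il17a in 19.4% ± 5.72. The naive sample had them in 14.5%, 0.999% and 0%, while Izumo1r was close (12.4% ± 5.64 against 12.9%). The name thus does not mean that these cells had stayed naive. An unnamed cluster led by Klrd1, Klrk1 and Gzma, genes of killer cells, held 6.32% ± 5.58. Klrd1 had a UMI in 66.3% of its cells and Klrk1 in 42.8%, but Gzma in only 5.43%, and 328 of its 516 cells were of mouse 3. Clusters of other cells were a photoreceptor-like cluster with Sag and Gnat1 (0.550% ± 0.619) and a macrophage or microglia-like cluster with Lyz2 and C1qa (1.03% ± 0.408). The 10 leading genes of the latter held 2 macrophage markers (Lyz2 and Tyrobp) and 3 genes of the dendritic cell list (H2-Ab1, H2-Aa and H2-Eb1). Another 2.08% ± 0.703 formed a cluster with 4 anergy markers up (Nt5e, Nr4a3, Tox and Cblb), which stayed unnamed because its median was 1955 UMIs and none of them was among its leading genes.

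Mice differed in this makeup. The regulatory T-like cluster held 20.5%, 35.3%, 11.02% and 32.2% of cells in mice 1 to 4, and the cycling clusters 22.5%, 9.48%, 25.3% and 6.24%. Naive cells made up clusters of their own: 76.0% lay in a naive T-like cluster with Ccr7, Lef1 and Dapl1, and 23.9% in an unnamed cluster led by the interferon-induced genes Ifit3, Ifit1 and Usp18. Clusters of 1 library may reflect that library, so sizes of T cell clusters were not compared between eye and naive cells.

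**Figure D1:**
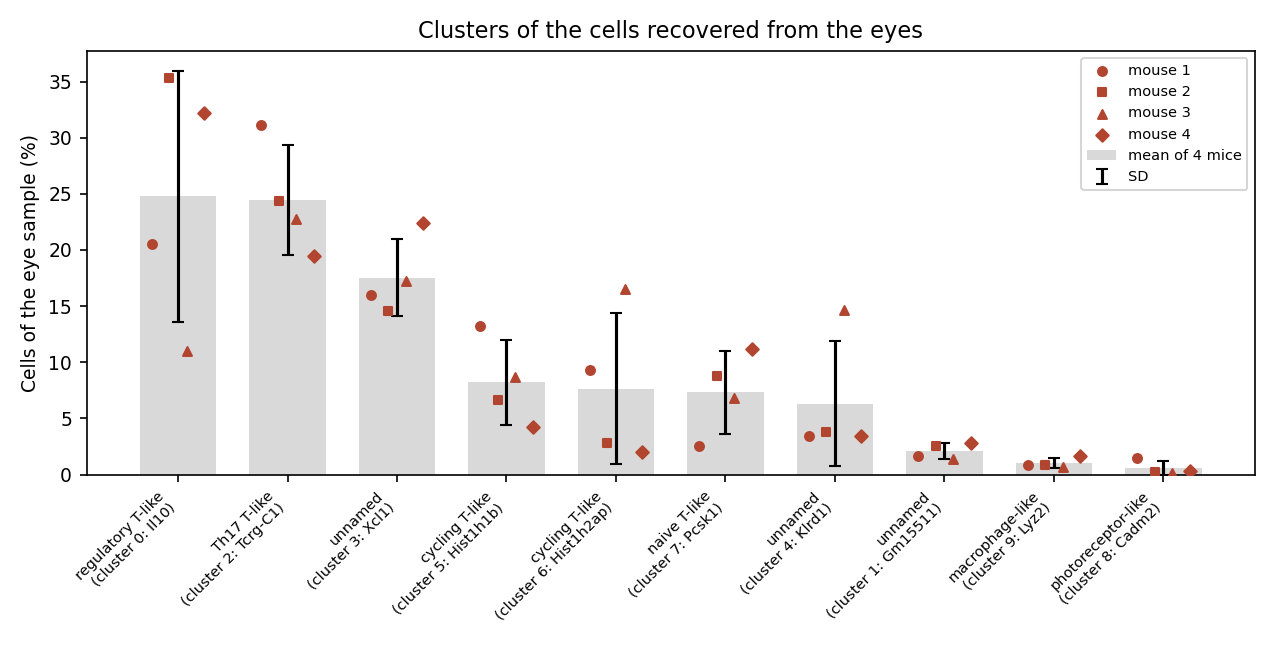
Share of each eye sample's cells in each cluster (percent), with bars for the mean of 4 mice, SD as error bars and a point per mouse. The regulatory T-like cluster averaged 24.8% and ranged from 11.02% to 35.3%, and the Th17-like cluster averaged 24.4%.

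The eye was compared with naive cells to ask how the recovered cells differed from the naive sample, and "rose" and "fell" stand for higher and lower than in it. Regulatory genes rose: Foxp3, the master transcription factor of regulatory T cells, was at 85.7 ± 35.4 CPM in the eye (SD, n = 4) against 7.61 in naive cells (log2 fold 3.49, SE 0.78). Ctla4, which blocks costimulation, rose from 88.4 to 1855 ± 379 CPM (log2 fold 4.39, SE 0.39), and Il2ra, the high-affinity interleukin-2 receptor chain, from 87.4 to 372 ± 111 (2.09, SE 0.40). Ikzf2, which encodes Helios, rose from 47.8 to 209 ± 65.0 CPM (2.13, SE 0.41). Il10 reached 106 ± 60.1 CPM against 0.141, from 1 naive count, a ratio of 754 (95% counting interval 135 to 29784). Of 25 regulatory genes tested, 20 rose and 0 fell (22 and 0 adjusted over the list alone), and Lrrc32, Gpr83, Izumo1r, Ikzf4 and Itgae were not called. The list had a median log2 fold of 3.48 and a camera adjusted p = 9.95e-08, but adjusted p = 0.278 with an estimated correlation.

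Genes of anergy moved with them. Nt5e, the ectoenzyme that makes adenosine, rose 111-fold (674 ± 112 CPM against 6.06, log2 fold 6.80, SE 0.38). The nuclear receptors Nr4a2 (6.40, SE 0.25) and Nr4a3 (4.20, SE 0.20) rose as well. In the same comparison dissociation stress genes were higher in 8 of 19, as given below. Whether handling of the tissue raised any anergy genes was not tested. Izumo1r was at 146 ± 68.4 CPM against 75.4 and was not called (log2 fold 0.95, SE 0.62, edgeR adjusted p = 0.248). Among 20 anergy genes 14 rose and 1 fell, also adjusted over the list alone, the latter being Dgka, a brake on receptor signalling. The median was 3.03 (2.36 with undetected genes at their bound) and the adjusted p = 8.00e-06, but adjusted p = 0.278 with an estimated correlation. Co-inhibitory receptors rose too: Lag3 went from 1.41 to 346 ± 62.5 CPM, 244-fold (log2 fold 7.93, SE 0.45), and Pdcd1, which encodes PD-1, from 1.55 to 146 ± 46.1 (6.55, SE 0.67). Tigit reached 45.6 ± 6.35 CPM, a ratio of 162 (interval 44.8 to 1335). Of 18 genes in that list, 13 rose and 3 fell, Cd244a, Eomes and Btla, with a median of 4.18 (adjusted p = 1.37e-05, but adjusted p = 0.278 with an estimated correlation).

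Transcripts of helper effector programs appeared that were not detected in naive cells. Il17a, the signature cytokine of Th17 cells, was at 476 ± 233 CPM against 0 counts, at least 1125-fold higher. Tbx21, the transcription factor of Th1 cells, was at 102 ± 4.20 CPM (at least 242-fold higher) and Ifng at 52.4 ± 32.1 (at least 124-fold). The chemokine receptor Ccr2 was at 153 ± 80.3 CPM (at least 361-fold) and the calcium-binding protein S100a4 at 1824 ± 424 (at least 4314-fold), each against 0 naive counts taken as 3. Th17 genes were called higher in 13 of 14 (14 adjusted over the list alone), with Rora at 669.9 ± 29.9 CPM against 26.4 and Ccr6 at 121 ± 12.5 against 3.24. Their median was 5.67 (5.14 bounded), with adjusted p = 1.05e-07. Th1 genes rose in 15 of 18, among them Ccl4 (143 ± 16.6 against 0.705 CPM) and Nkg7 (393 ± 63.4 against 1.97), with a median of 4.61 and adjusted p = 9.95e-08. Both lists had adjusted p = 0.131 with an estimated correlation.

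Type 1 regulatory genes, of Il10-producing cells that lack Foxp3, rose in 10 of 13 and fell in 1, Eomes, with Maf at 853 ± 198 against 8.17 CPM, 104-fold. The list had a median of 5.07 (4.39 bounded, adjusted p = 3.37e-04, but adjusted p = 0.284 with an estimated correlation). Th2 genes rose in 5 of 10, Il1rl1, Areg, Pparg, Ccr4 and Nfil3, and fell in 1, Il17rb (median 6.06, 3.88 bounded, adjusted p = 0.0483, but adjusted p = 0.284 with an estimated correlation). Areg had a ratio of 287 (interval 51.5 to 11324). Cytotoxic genes rose in 6 of 13, Ctsw (3.76) among them, and fell in 1, Serpinb9 (median 3.25, 2.37 bounded, adjusted p = 0.0348, but adjusted p = 0.547 with an estimated correlation). Follicular helper genes rose in 5 of 11, Icos, Pdcd1, Tox2, Il21 and Cd200, and fell in 2, Il6st and Btla, and did not pass as a list (median 0.40, adjusted p = 0.105).

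Genes of naive and resting cells fell. Ccr7, the chemokine receptor for lymph node entry, fell from 178 to 49.9 ± 18.2 CPM (log2 fold −1.83, SE 0.39). The transcription factors Lef1 (1573 to 196 ± 31.2 CPM, −3.01, SE 0.19) and Klf2 (290.1 to 63.3 ± 9.27, −2.20, SE 0.18) fell too. The naive list fell in 17 of 20 and rose in 1, Il7r (median −2.49, adjusted p = 8.00e-06, but adjusted p = 0.284 with an estimated correlation). The largest falls above the expression minimum were in Fgf13 (295 to 5.38 ± 4.10 CPM, 54.5-fold), Nsg2 (−5.61, SE 0.50) and Nedd4l (−5.22, SE 0.52). Cd44, an activation marker, rose from 26.8 to 236 ± 18.9 CPM (3.14, SE 0.19). Activation genes rose in 12 of 20 and fell in 1, Myc (median 1.77, adjusted p = 3.70e-04, but adjusted p = 0.284 with an estimated correlation).

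Proliferation genes rose and interferon-induced genes fell. Mki67, present in dividing cells, rose from 22.4 to 339 ± 149.8 CPM (log2 fold 3.92, SE 0.74). Of 52 genes of G2 and M phase, 40 rose and 1 fell, Smc4 (median 3.03, adjusted p = 9.71e-07). Of 41 S phase genes 20 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 1.72 and adjusted p = 1.11e-05. Glycolysis genes rose in 9 of 15 (10 adjusted over the list alone), Hk2 by 3.99 and Pkm by 1.40, with a median of 1.40 and adjusted p = 5.18e-04. Oxidative phosphorylation genes rose in 15 of 25, among them Cox8a by 1.49, with a median of 1.07 and adjusted p = 6.45e-05. These 4 lists had adjusted p = 0.547 each with an estimated correlation. Of 30 interferon-induced genes 22 fell and 0 rose (23 and 1 adjusted over the list alone), with Usp18 going from 128 to 5.51 ± 1.35 CPM and Oasl2 from 57.9 to 1.60 ± 0.510. The interferon-led cluster, 23.9% of the naive cells, held 72.2% of the naive sample's Usp18 UMIs and 84.7% of its Oasl2 UMIs. The other naive T cells had 49.2 and 12.3 CPM of these genes, and 21 of the 22 genes were above the eye mean in them. That list's median was −1.85 (adjusted p = 9.81e-07, but adjusted p = 0.477 with an estimated correlation).

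Tissue residency genes rose in 10 of 15 and fell in 0 (12 and 0 adjusted over the list alone), with the chemokine receptor Cxcr6 at 154 ± 19.7 against 5.36 CPM. Their median was 3.89 (3.74 bounded, adjusted p = 1.59e-06, but adjusted p = 0.131 with an estimated correlation). TGF-beta response genes rose in 7 of 16, Tgif1 by 3.34 and Skil by 2.14, and fell in 2, Id3 and Smad3 (8 and 2 adjusted over the list alone). The median was 2.07 (1.99 bounded, adjusted p = 0.00359, but adjusted p = 0.278 with an estimated correlation). Chemokine receptors and integrins rose in 9 of 16 and fell in 2, Ccr7 among them (median 1.47, adjusted p = 0.00114, but adjusted p = 0.284 with an estimated correlation). Dissociation stress genes, which rise when tissue is taken apart, were higher in 8 of 19, with Fosb at 128 ± 12.8 against 6.20 CPM, and lower in 1, Zfp36 (median 0.70, adjusted p = 0.0387, but adjusted p = 0.374 with an estimated correlation). Retinoic acid response genes rose in 4 of 14, Itga4, Dhrs3, P2rx7 and Hic1, and did not pass as a list (median 0.96, 0.63 bounded, adjusted p = 0.147). Cholesterol synthesis (3 of 19 up, Cyp51, Insig1 and Stard4, median 0.09, adjusted p = 0.948) and apoptosis (4 of 16 up, Bcl2a1b, Bcl2a1d, Cdkn1a and Pmaip1, and 2 down, Bcl2 and Fas, median 0.13, adjusted p = 0.378) did not pass either.

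Marker genes of other cell types were tested as well. Lyz2, a macrophage gene, was at 2.05 ± 0.141 CPM in eye T cells, with 0 naive counts. Macrophage markers rose in 7 of 9 (median 2.61, 0.95 bounded, adjusted p = 0.00658, but adjusted p = 0.278 with an estimated correlation). Photoreceptor markers rose in 3 of 10, Rp1 and Gngt1 among them, fell in 1, Pde6b, and did not pass (median 4.29, 1.05 bounded, adjusted p = 0.0730). Dendritic cell markers (1 of 4 up, H2-Ab1, 0 adjusted over the list alone, median 1.72, adjusted p = 0.107) did not pass. Of 3 Mueller glia markers 0 were called by edgeR, DESeq2 or limma-voom, with 1 higher at an unadjusted p under 0.05 (list adjusted p = 0.409). Lens markers (Crybb3 up and Cryba1 down of 3, median 6.91, 0.75 bounded, adjusted p = 0.555) did not pass. B cell markers (1 of 4 up, Ebf1) had a median of −0.07 but a mean of 0.50 and an upward test (adjusted p = 0.948).

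By edgeR's quasi-likelihood test 2549 genes were higher and 2015 lower in eye cells, of 14791 tested. Limited to cells with Xist and no Y-linked UMIs, 1238 genes were lower, and Xist-only cells were 12.9% to 16.7% of the sexed eye cells and 52.0% of the sexed naive cells. Under upper-quartile scaling the median log2 fold of all genes moved from 0.08 to −0.12 and the share of calls that were higher from 55.9% to 45.1% (46.1% with limma-voom). Eye and naive cells came from different captures.

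The same genes were counted per cell to ask how many cells carried each transcript. At 2000 UMIs, Foxp3 was found in 14.0% ± 5.82 of eye T cells (SD, n = 4) and in 1.53% of naive cells (exact 95% interval 0.974% to 2.29%). In mice 1 to 4 it was in 13.2%, 19.7%, 6.23% and 16.8%. Nt5e was found in 62.8% ± 5.84 against 0.999% (0.560% to 1.64%), Ctla4 in 89.3% ± 3.63 against 14.5% (12.7% to 16.3%), and Il10 in 11.5% ± 5.36 against 0, which allows a share of up to 0.1999%. Cells with both Izumo1r and Nt5e and no Foxp3 made up 11.95% ± 4.96 of Foxp3-negative eye cells, and 0 in naive cells, which allows up to 0.203%. Il17a was in 22.9% ± 6.22 of eye cells, Ifng in 5.12% ± 2.03 and Lag3 in 43.3% ± 3.88, while Ccr7 was in 6.37% ± 2.08 against 27.6%. Izumo1r alone was in 21.1% ± 8.54 against 12.9% (11.3% to 14.7%), with 1 eye sample below the naive value (two-sided exact permutation p = 0.8). For the other measures the exact permutation p = 0.2, the smallest that 5 samples allow.

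Photoreceptor-like cells, in which free RNA can be read, had Foxp3, Izumo1r, Il10, Ifng and Tigit in 0 of 32 cells past 2000 UMIs (median of all 35, 6568 UMIs, against 8781 to 13990 in eye T cells), Ctla4 in 9.38%, Ikzf2 in 15.6% and Nt5e, also a marker of rods, in 31.2%. A count of 0 there allows up to 9.38%, which is above the Ifng and Tigit means of eye T cells (5.12% and 8.83%), the Foxp3 share of mouse 3 (6.23%), its share with Izumo1r and Nt5e but no Foxp3 (6.39%) and the Il10 shares of mice 1 and 3 (8.17% and 5.99%). In Th17-like cells of the same capture, Foxp3 was in 0.412% in mouse 3, and Il10 in 0.504% and 0.206% in mice 1 and 3. These values argue against free RNA as the source of those Foxp3 and Il10 shares. The Ifng, Tigit and Izumo1r with Nt5e shares were not judged this way. Il17a, Lag3 and Pdcd1 were each in 1 of the 32 cells. The Ikzf2 share of eye T cells, 17.5% ± 3.76, was close to that of the photoreceptor-like cells. By cluster it was 4.95% ± 2.19 in naive T-like, 6.66% ± 3.78 in Th17-like and 29.5% ± 9.04 in regulatory T-like cells of the eye. The 2 low shares argue against free Ikzf2 RNA at 15.6% in eye T cells. Without thinning, Foxp3 was found in 30.9% ± 8.57 of eye cells and 3.17% of naive cells, and Izumo1r with Nt5e in 33.2% ± 4.78 and 0.401%.

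**Figure D2:**
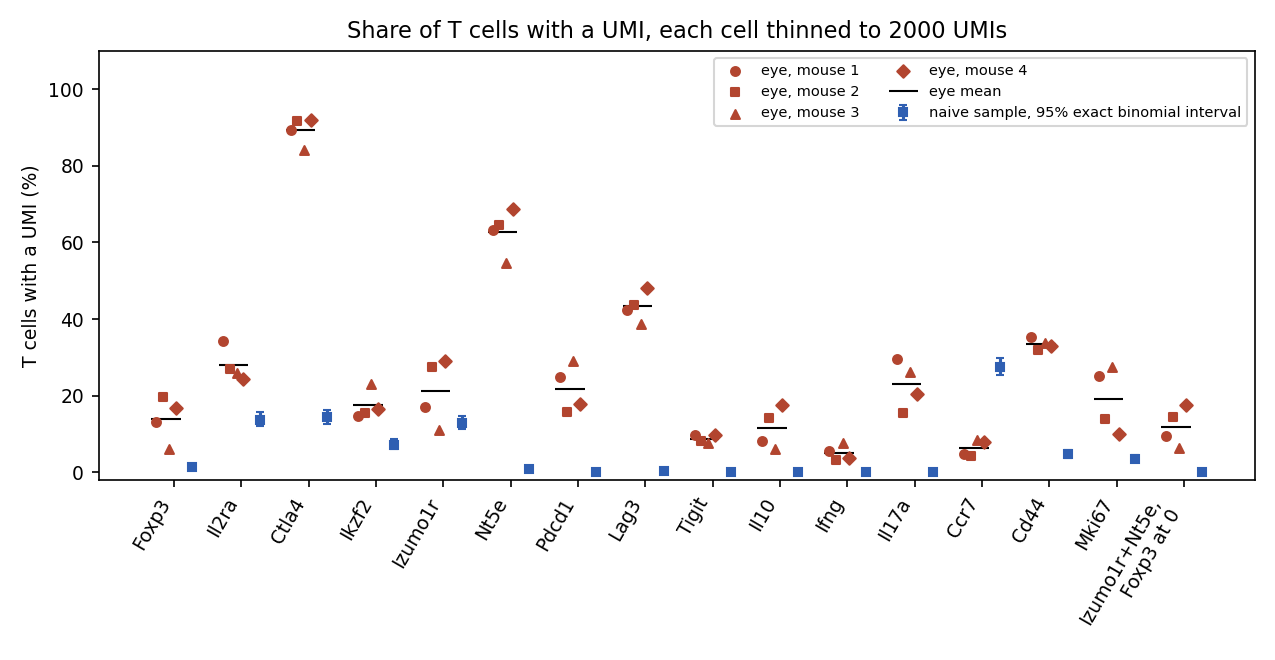
Share of T cells with at least 1 UMI of each gene after thinning to 2000 UMIs (percent), with a point per eye mouse, a line at the mean of 4 mice and the naive sample with its exact 95% interval. Nt5e averaged 62.8% in the eye against 0.999% in naive cells, while Ccr7 averaged 6.37% against 27.6%.

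Eye T cells with Foxp3 transcripts were compared with those without, within each mouse, to ask what set the regulatory cells apart. Il10 was 11.04-fold higher, at 260.3 ± 128 CPM against 24.5 ± 12.9 (SD, n = 4, log2 fold 3.46, SE 0.12). Gzmb, a cytotoxic protease, was at 123 ± 52.6 against 9.50 ± 2.94 CPM (3.67, SE 0.16), Ccr2 at 344 ± 154 against 45.4 ± 19.6 (2.94, SE 0.09) and Il2ra at 804 ± 232 against 156 ± 54.2 (2.39, SE 0.07). Lower were Il17a, at 88.5 ± 33.1 against 670.0 ± 363 CPM (−2.87, SE 0.23), Tnfsf8, which encodes the CD30 ligand (−3.37, SE 0.34), Xcl1, a chemokine for dendritic cells (−3.03, SE 0.38), and Tcf7, a factor of naive and memory cells (−2.58, SE 0.12). Each of these genes moved the same way in 4 of 4 mice.

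Regulatory genes rose in 20 of 24 and fell in 3, Tgfb1, Nrp1 and Ebi3. Lrrc32, which presents latent TGF-beta, was at 2.62 (SE 0.10), Tnfrsf4 at 1.67, Tnfrsf9 at 1.56 and Ikzf2 at 1.32. The list's median was 1.26 (adjusted p = 3.46e-07, but adjusted p = 0.256 with an estimated correlation). The anergy list split: 6 genes rose and 12 fell of 20 (median −0.32, adjusted p = 0.178). Izumo1r was higher, at 269 ± 112 against 78.3 ± 35.1 CPM (1.79, SE 0.08), as was Lag3 (1.23, SE 0.07), while Nr4a3 was lower (−1.45, SE 0.11). Nt5e moved little, at 762 ± 149 against 624 ± 103 CPM (0.29, SE 0.08, edgeR adjusted p = 0.0188), and was higher in 3 of 4 mice. Co-inhibitory receptors also split, with 9 of 17 up and 7 down (median 0.74, mean −0.00, adjusted p = 0.512). Tigit rose by 1.32 and Ctla4 by 0.93 on the log2 scale, while Pdcd1 fell by 1.12 and Btla fell by 2.01.

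Type 1 regulatory genes rose in 10 of 12, Prdm1 (1.79) among them, and fell in 1, Il21 (median 1.03, adjusted p = 1.92e-04, but adjusted p = 0.448 with an estimated correlation). Th17 genes fell in 10 of 14, among them Il17f (−4.28) and Ccr6 (−2.04), and rose in 3, Il1r1, Ahr and Ltb4r1. Their median was −1.53 (adjusted p = 0.00431, but adjusted p = 0.545 with an estimated correlation). Follicular helper genes fell in 8 of 11, among them Tox2 (−2.15) and Bcl6 (−1.59), and rose in 3, Icos, Slamf6 and Il6st (median −1.12, adjusted p = 0.00431, but adjusted p = 0.448 with an estimated correlation). Naive genes fell in 12 of 20 (13 adjusted over the list alone) and rose in 5, among them Txnip, S1pr1, Klf2 and Ly6c1, while the list's median was −0.66 (adjusted p = 0.00611, but adjusted p = 0.448 with an estimated correlation). Th1 genes rose in 7 of 17, Ccl4 (2.31) and Cxcr3 (1.54) among them, and fell in 5, Il18r1, Il18rap, Stat4, Fasl and Tnf (adjusted p = 0.396). Ifng was not called (−0.31, SE 0.37, edgeR adjusted p = 0.558), nor were Ccr7 and Cd44.

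Cycle and interferon genes were higher as groups, by smaller folds. G2 and M phase genes rose in 44 of 52 (47 up and 1 down adjusted over the list alone), with Mki67 at 0.75 (SE 0.09), a median of 0.58 and adjusted p = 3.17e-12. S phase genes rose in 29 of 41 and fell in 1, Atad2 (33 and 2 adjusted over the list alone), with Mcm4 at 0.58, a median of 0.40 and adjusted p = 7.51e-07. Interferon-induced genes rose in 17 of 29 (19 up and 2 down adjusted over the list alone), among them Iigp1 (2.10), Gbp7 (1.65) and Irf1 (1.23), with a median of 0.52 and adjusted p = 2.12e-05. Oxidative phosphorylation genes rose in 19 of 25 (Uqcr11 0.55, median 0.22, adjusted p = 1.11e-04) and glycolysis genes in 8 of 15 (9 adjusted over the list alone, Pkm 0.57, median 0.30, adjusted p = 0.00416). These 5 lists had adjusted p = 0.545 each with an estimated correlation. With the gate set at 2000 UMIs, Mki67 was at −0.0616.

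The remaining lists did not pass. Activation genes rose in 7 of 20 and fell in 5, Nfkbid, Egr2, Egr3, Nr4a1 and Cd40lg (adjusted p = 0.329). Th2 genes rose in 3 of 6, Pparg, Ccr4 and Nfil3, and fell in Areg (4 and 1 adjusted over the list alone, adjusted p = 0.265). TGF-beta response genes rose in Ctla4 and Itgae and fell in Pmepa1, Id3, Ski and Ldlrad4, of 14 (adjusted p = 0.515). Residency genes rose in Prdm1, Itgae and Ahr and fell in Cxcr4, Rgs2, Rgs1, P2rx7 and Bhlhe40, of 15 (adjusted p = 0.396). Chemokine receptors and integrins rose in 8 of 16, Itgb7 (1.33) among them, and fell in 3, Cxcr4, Itgal and Ccr6 (8 and 4 adjusted over the list alone, adjusted p = 0.279). Cholesterol synthesis genes rose in 5 of 19, among them Idi1, Fdft1 and Nsdhl (adjusted p = 0.178). Stress genes rose in Zfp36 and Dnajb1 and fell in Btg2, Atf3, Fosb and Dusp1, of 18 (2 and 5 adjusted over the list alone, adjusted p = 0.259). Apoptosis genes rose in Mcl1, Trp53inp1 and Bbc3 and fell in 7 of 16, Bcl2 among them (4 and 8 adjusted over the list alone, adjusted p = 0.216). Cytotoxic genes rose in Nkg7, Prf1 (2.68), Gzmb and Lgals1 and fell in Fasl, Klrd1, Klrk1, Serpinb6b and Ctsw (−1.54), of 11 (4 and 6 adjusted over the list alone). Their median was −0.56, the mean 0.13 and the test downward (adjusted p = 0.986). Retinoic acid genes rose in Itga4, Ccr9, Rara and Itgb7 and fell in Tgm2, Crabp2, Dhrs3 and P2rx7, of 12, with a median of −0.01, a mean of −0.02 and an upward test (adjusted p = 0.726). Of 3 B cell markers 1 rose, Ighm at 1.79 (adjusted p = 0.279). Macrophage (5 tested, adjusted p = 0.444), dendritic cell (4 tested, adjusted p = 0.825) and photoreceptor markers (5 tested, adjusted p = 0.726) had 0 calls by edgeR and by DESeq2, with 1 dendritic cell marker and 0 of the others at an unadjusted p under 0.05.

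In total 2332 genes were higher and 2092 lower in Foxp3-positive cells, of 12142 tested with the mouse as a block (edgeR). Without the block the counts were 1013 and 1098. A cell without a Foxp3 UMI can still express Foxp3, and 412 to 731 positive cells per mouse were set against 903 to 1794 negative cells.

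Among Foxp3-negative eye cells, those with transcripts of both FR4 and CD73, the surface pair used to mark anergic cells, were compared with those with neither. Il10 stood out, at 48.1 ± 24.3 against 5.60 ± 4.12 CPM (SD, n = 4), 8.57-fold higher (log2 fold 3.10, SE 0.25). The negative sums held 547658, 670390, 1910937 and 733504 UMIs in mice 1 to 4, so their Il10 level rests on few UMIs and the size of the fold is uncertain. Also higher were the cell cycle genes Mki67, at 345 ± 179 against 140 ± 85.3 CPM (1.33, SE 0.12), and Cenpf, at 123 ± 68.5 against 38.0 ± 32.0 (1.63, SE 0.18). Lag3 was at 267 ± 33.4 against 156 ± 33.0 CPM (0.73, SE 0.14) and Il2ra at 207 ± 86.8 against 101 ± 54.1 (0.99, SE 0.14). Lower were Il23r, the interleukin-23 receptor of Th17 cells (−1.74, SE 0.23), and the co-inhibitory receptor Cd160, at 26.9 ± 3.98 against 72.7 ± 14.5 CPM (−1.43, SE 0.16). Each moved the same way in 4 of 4 mice. Without the regulatory T-like cluster and the cycling cluster with Foxp3 in 24.4% of its cells at 2000 UMIs, Il10 was at 0.88 (SE 0.42, adjusted p = 0.314) and Lag3 at 0.48, and neither was called.

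The anergy list itself did not pass (median −0.06, adjusted p = 0.392). Of its 17 genes tested 1 was higher, Lag3, and 4 were lower, Nr4a2 (−0.53, SE 0.10), Nr4a3, Nrp1 (−0.67, SE 0.11) and Dgka (−0.42, SE 0.09), or 2 and 4 adjusted over the list alone. Dgka turned to 0.0608 with the gate set at 2000 UMIs and to 0.20 with Izumo1r alone as the gate. Pdcd1 (0.02, edgeR adjusted p = 0.970), Tigit (0.35, adjusted p = 0.408) and Ikzf2 (0.30, adjusted p = 0.587) were not called. Type 1 regulatory genes rose in 7 of 10 and fell in 0, with Maf at 0.93 (SE 0.09), Prdm1 at 0.87 (SE 0.18) and Il21 at 1.05 (SE 0.23, −0.0479 with Izumo1r alone). Their median was 0.64 and the adjusted p = 1.92e-05, but adjusted p = 0.210 with an estimated correlation. Regulatory genes rose in 6 of 21 and fell in 1, Nrp1 (8 and 1 adjusted over the list alone), with a median of 0.36 (adjusted p = 2.79e-04, but adjusted p = 0.352 with an estimated correlation). The co-inhibitory list rose in 4 of 17, Ctla4 (0.43), Lag3 and the transcription factors Maf and Prdm1, and fell in 1, Cd160 (4 and 2 adjusted over the list alone). Its adjusted p = 0.0441 became 0.0583 without the mouse block and adjusted p = 0.454 with an estimated correlation.

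Cell cycle genes were higher as groups. G2 and M phase genes rose in 40 of 51 (47 adjusted over the list alone), with a median of 1.05 (adjusted p = 6.01e-32, but adjusted p = 0.210 with an estimated correlation). S phase genes rose in 18 of 40 (33 adjusted over the list alone), among them Clspn (1.11) and Dtl (0.80), with a median of 0.69 (adjusted p = 4.60e-17, but adjusted p = 0.185 with an estimated correlation). With cells matched on total UMIs, the median of the 40 called G2 and M phase genes went from 1.26 to 0.39, with 3 of the 31 still tested called. With the gate set at 2000 UMIs, Mki67 turned to −0.41, Cenpf to −0.41, Clspn to −0.56 and Dtl to −0.19. Median UMIs in the main gate were 11890, 9210, 18251 and 9613 in positive and 6308, 6479, 9394 and 5929 in negative cells of mice 1 to 4. In the gate set at 2000 UMIs the negative cells were the deeper ones. Medians there were 10911, 8805, 13260 and 8826 in positive and 12119, 9854, 16224 and 9428 in negative cells. Its negative cells in mouse 1 numbered 358, against 77 in the main gate, so that setting changed depth and the choice of cells together.

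Naive genes fell in 6 of 20 (12 adjusted over the list alone) and rose in 0. Klf2 was at −0.92 (SE 0.22, lower in 3 of 4 mice), Il7r at −0.57 and Satb1 at −0.44, and the list's median was −0.48 (adjusted p = 3.05e-05, but adjusted p = 0.266 with an estimated correlation). Th1 genes fell in 3 of 17, Cxcr6 (−0.60), Stat4 (−0.55) and Il18rap, and rose in 1, Ccl3 (1 up and 5 down adjusted over the list alone). Their median was −0.18 (adjusted p = 0.00457, but adjusted p = 0.358 with an estimated correlation). Stress genes fell in 4 of 17, Btg2, Ier5, Junb and Fosb (−0.54), or 1 up and 7 down adjusted over the list alone, with a median of −0.21 (adjusted p = 0.00226, but adjusted p = 0.210 with an estimated correlation). Interferon-induced genes fell in 1 of 26, Ifi206 (6 adjusted over the list alone, median −0.19). Their adjusted p = 0.00336 became 0.0522 without the mouse block and adjusted p = 0.266 with an estimated correlation. Cytotoxic genes fell in 2 of 10, Serpinb6b and Klrd1 (−0.74, lower in 3 of 4 mice), and rose in 1, Lgals1 (2 up and 5 down adjusted over the list alone), with a median of −0.35 (adjusted p = 0.0332, but adjusted p = 0.454 with an estimated correlation). With the gate set at 2000 UMIs Satb1 turned to 0.19, Cxcr6 to 0.18, Ifi206 to 0.41 and Junb to 0.0676, and with Izumo1r alone Satb1 turned to 0.36 and Klrd1 to 0.29. Ccl3 was at −0.26 with matched cells and −0.43 without the regulatory T-like cluster, and Il7r at 0.0357 with both changes.

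Metabolic lists passed with few or 0 calls. Glycolysis genes rose in 1 of 15, Ldha (5 up and 1 down adjusted over the list alone), and the list's adjusted p = 0.0156 became 0.202 without the block and adjusted p = 0.352 with an estimated correlation. Of 25 oxidative phosphorylation genes 0 were called by edgeR or DESeq2, with 8 higher at an unadjusted p under 0.05. That list's adjusted p = 0.0156 became 0.162 without the block and adjusted p = 0.452 with an estimated correlation. Of 19 cholesterol synthesis genes 0 were called by edgeR or DESeq2, with 1 higher at an unadjusted p under 0.05. Here the adjusted p = 0.0406 became 0.109 without the block and adjusted p = 0.287 with an estimated correlation.

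Th17 genes rose in 3 of 13, Ccl20, Ahr and Ltb4r1, and fell in 2, Il23r and Tmem176a (4 and 5 adjusted over the list alone), with a median of −0.19, a mean of 0.09 and a downward test (adjusted p = 0.552). Il17a was not called (0.81, edgeR adjusted p = 0.165). Activation genes rose in 3 of 19, Icos, Il2ra and Irf4 (median −0.07, mean 0.07, adjusted p = 0.985). Of 6 Th2 genes 0 were called by edgeR or DESeq2, with 1 lower at an unadjusted p under 0.05 and adjusted over the list alone (list adjusted p = 0.985). Follicular helper genes rose in 2 of 11, Icos and Il21 (adjusted p = 0.245), and TGF-beta response genes in 3 of 14, Ctla4, Tgfbr1 (0.51) and Pmepa1 (0.73, adjusted p of the list = 0.165). Retinoic acid genes rose in 1 of 9, Ccr9 at 1.21 (1 and 1 adjusted over the list alone, adjusted p = 0.385). Residency genes rose in Prdm1 and Ahr and fell in Cxcr6, of 15 (adjusted p = 0.683). Chemokine receptors and integrins rose in Ccr2 and fell in Itgb1 and Cxcr6, of 16 (1 and 3 adjusted over the list alone), with a median of −0.02, a mean of 0.01 and a downward test (adjusted p = 0.985). Apoptosis genes rose in 1 of 15, Trp53inp1 (3 and 1 adjusted over the list alone), with a median of −0.02, a mean of −0.01 and an upward test (adjusted p = 0.985). With Izumo1r alone as the gate Icos turned to −0.0304, Irf4 to −0.0580 and Ccl20 to −0.18, and without the regulatory T-like cluster Ccr2 was at −0.0346. With that Foxp3-rich cycling cluster left out as well, Ccr2 was at −0.55 and Ccr9 at −0.15.

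By edgeR with the mouse as a block, 317 genes were higher and 157 lower, of 10233 tested, with 266 to 526 positive and 77 to 173 negative cells per mouse. Without the block, edgeR called 0 genes (387 higher and 320 lower at an unadjusted p under 0.05). DESeq2 with the mouse as a term called 184 and 91. With cells matched on UMIs 86 and 33 were called, of which 59 and 24 were among the 317 and 157. Without cells with Mki67 or Top2a 46 and 24 were called (38 and 24 of them shared), and with the gate at 2000 UMIs 801 and 650 (68 and 40 shared). The counts were 186 and 105 without mouse 1, 194 and 85 without mouse 2, and 153 and 89 without mouse 3. Of the positive cells, 12.7% lay in the regulatory T-like cluster, against 3.90% of the negative cells, and without that cluster Il10 was at 1.87 (adjusted p = 0.00626).

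**Figure D3:**
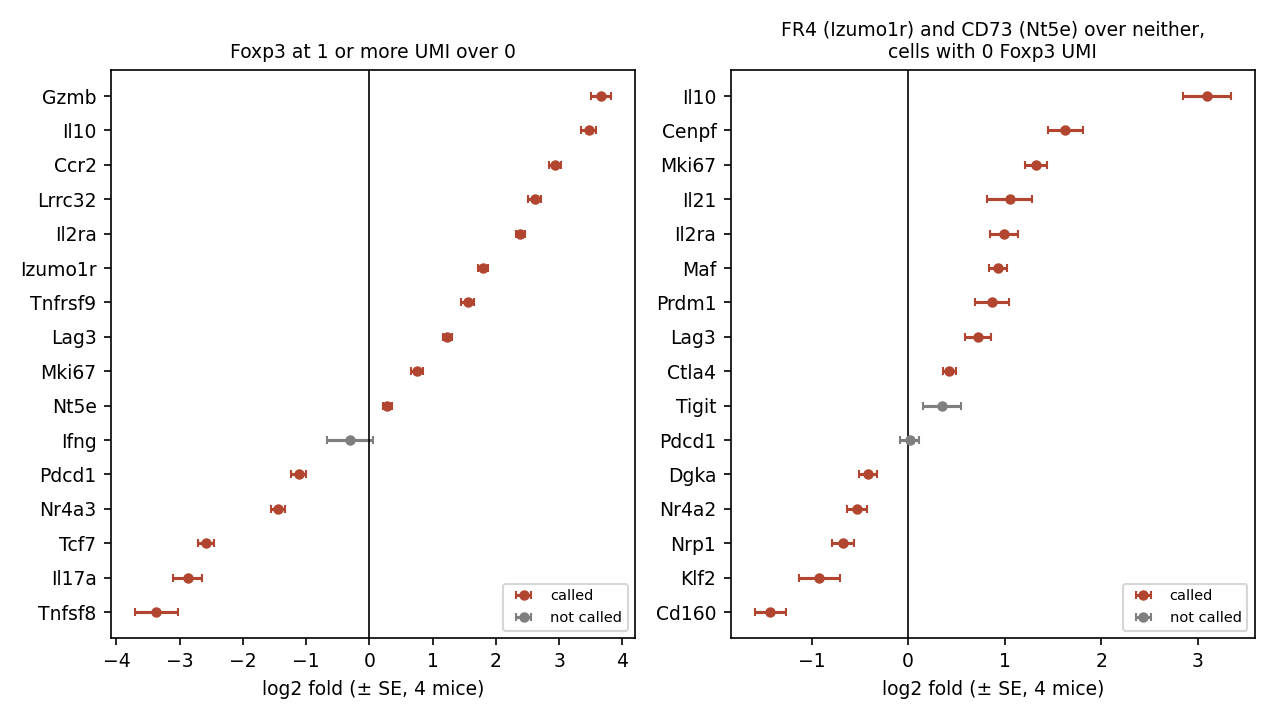
Log2 fold with its standard error for 16 genes in the Foxp3 gate (left, positive against negative cells) and 16 in the FR4 CD73 gate (right), 4 mice each, with grey points for genes not called. Il10 was higher in both, at 3.46 and 3.10, while Nr4a2 was lower in the FR4 CD73 gate, at −0.53.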

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

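The explanation tests in this part were chosen after the result they address was seen. The depth settings they use had been planned, and the settings limited to cells of 1 sex or without the regulatory T-like cluster, alone or with a Foxp3-rich cycling cluster, had not. A value far from the other 3 mice is given for 13 of 247 values examined, and chance alone would single out about 1 in 20 groups.

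In mouse 3, the cluster led by Klrd1, Klrk1 and Gzma held 14.7% of cells, against 3.39% to 3.77% in the other mice. The photoreceptor-like cluster held 1.47% of cells in mouse 1 and 0.179% to 0.326% in the others. Ccl4 was at 118 CPM in mouse 2 (149.9 to 153 in the others), Il23r at 34.6 in mouse 4 (21.7 to 23.4), Junb at 1382 in mouse 3 (1526 to 1554) and Ikzf2 at 305 in mouse 3 (166 to 188).

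In the Foxp3 gate, Ifng had a log2 ratio of 1.197 in mouse 3 but −0.96 to −1.17 in the other mice, so the gene that was not called over 4 mice went opposite ways in them. Il2ra stood at 2.60 in mouse 4 (2.27 to 2.32), Tnfrsf9 at 1.98 in mouse 1 (1.36 to 1.43) and Uqcrq at 0.20 in mouse 3 (0.39 to 0.41). In the FR4 CD73 gate, Ikzf2 was at −0.67 in mouse 3 and 0.92 to 1.22 in the others, Ube2c at 3.46 in mouse 4 (1.24 to 1.56) and Dgka at −0.24 in mouse 1 (−0.41 to −0.44).

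Cells outside the comparisons also gave a signal. Photoreceptor-like cells made up a mean of 0.550% of eye cells and 0 of the naive sample, and macrophage or microglia-like cells a mean of 1.03%, against 0.0644% of the naive sample, though their 10 leading genes held 3 of the dendritic cell list (H2-Ab1, H2-Aa and H2-Eb1) against 2 macrophage markers. Both appeared in cells sorted as donor T cells.

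The first pattern is the size of the difference between eye and naive cells, 4564 called genes such as Nt5e, Lag3 and Ccr7. Depth is argued against as the whole cause, since 86.5% of those genes stayed called in the same direction with all sums at the smallest total. So is the sex of the donor cells: 88.9% of the 4564 genes, of which 4308 could be tested, kept their direction and a fold of at least 2 in cells with Y-linked and no Xist UMIs. The capture cannot be told apart from the group, because 0 captures held both kinds of sample. The transfer, the eye and the time since injection also stay open, as untested biological explanations.

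The second pattern is Il10 and the cell cycle genes in the FR4 CD73 gate. Regulatory cells whose Foxp3 was missed may be a cause of the Il10 difference, though a first test, without the regulatory T-like cluster, met the mark set against that: the log2 fold fell from 3.10 (SE 0.25) to 1.87 (SE 0.35, adjusted p = 0.00626), which is above 1 and still called. A second test, added after that outcome, took the fold to 0.88 (SE 0.42, adjusted p = 0.314, and from 3.73e-27 to 0.314 over all alternatives) by leaving out as well the cycling cluster with Foxp3 in 24.4% of its cells at 2000 UMIs, though both clusters were rich in Il10, so that leaving them out can lower it by construction. Depth is argued against for Il10, at 4.18 (SE 0.32) with cells matched on total UMIs, though the matched negative sums held only 519090 to 1825434 UMIs. Depth may be a cause for the 40 called G2 and M phase genes: matching took their median from 1.26 (SD 0.33) to 0.39 (SD 0.33). Of the 31 genes tested 3 were still called, with fewer cells in the sums. The cycling T-like clusters had high median UMIs, 18722 and 23989, so matching on UMIs also evens out the cycling cells. Depth and a true difference in cycling both forecast such a fall, and the test cannot part them. A link of FR4 and CD73 to division or to Il10 stays open.

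The third pattern is Tcrg-C1 and Tcrg-C2 transcripts in the Th17-like cluster, found in 37.4% ± 8.31 of its cells at 2000 UMIs (SD, n = 4). Free RNA is argued against, since that share was 48.8 times the share in the regulatory T-like cluster. Gamma-delta T cells are argued against as the main source by Cd4 alone. It was found in 54.4% ± 2.86 of Tcrg-positive eye T cells of all clusters, 115% of its share in other eye T cells. Those others include regulatory T-like and cycling cells with lower Cd4 shares. Trdc, the delta constant gene, was found in 4.79% ± 0.841 of Tcrg-positive cells and 2.99% ± 1.29 of the others, and was higher in 4 of 4 mice. Gamma-delta T cells forecast Trdc in most Tcrg-positive cells, which was not seen, but how well Trdc is detected here is not known. The alpha constant gene Trac, in 14.7% ± 1.48 of Tcrg-positive cells, is no gauge of that, since the donors lack Tcra. Trbc2, at 98.8% of its share in the others, was common in all T cell clusters and cannot part the lineages. Trav16, at 74.4%, fell just short of the mark set against gamma-delta T cells. Transcription of the gamma locus in Il17a-positive alpha-beta cells is a hypothesis that these values leave open.

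Other splits of the samples were also run. With the naive place given to each sample in turn, 1 of 5 splits called as many genes as the real one (4564, against a highest other of 0), too few splits for a share under 0.05. In the gates the mouse pairs the sums, so the real split was set against the splits that part every mouse. With the block, 1 of 8 called as many in each gate (4424 and 474, against 0 and 0), and 8 splits are too few for a share under 0.05. The other 27 splits put both sums of at least 1 mouse on the same side and were run without the block. They called up to 331 genes in the Foxp3 gate, where the real split called 2111 without the block. For the FR4 CD73 gate they called up to 609, where the real split called 0 by edgeR (387 and 320 at an unadjusted p under 0.05). Both highest counts came from the split that parted mice 1 and 3 from mice 2 and 4, which points to a structure of the samples that the block removes.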

How the results depend on the processing

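Settings limited to cells of 1 sex, without the low-UMI cluster, without the highest-UMI cells, without the highest doublet scores or without the regulatory T-like cluster (alone, or with the Foxp3-rich cycling cluster) were chosen after seeing the data, and the others were not. For named genes, 1811 of 1842 values in the eye comparison kept direction and call, 30 lost the call and 1 reversed. In the Foxp3 gate 1159 of 1187 did, with 16 lost, 11 gained and 1 reversed, and in the FR4 CD73 gate 1009 of 1284, with 222 lost, 12 gained and 41 reversed. In the gates, the values without doublet removal repeat the main ones almost by construction, since only 1 eye cell was marked. Unless a reason is given, the cause was not tested. Depth limits the shares and the gates, since a deeper cell passes a gate more often, and the naive sample had the fewest UMIs.

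Counts in the eye comparison stayed within 1.5 times, at 2266 to 2579 higher and 1755 to 1957 lower with a mouse left out, except 1238 lower genes in Xist-only cells, where fewer cells were summed. In the Foxp3 gate, counts were 1013 higher and 1098 lower with no replicate block, where mouse differences enter the error, and 1574 to 2174 and 1491 to 1994 with a mouse left out. In the FR4 CD73 gate (317 and 157), no replicate block gave 0 and 0 by edgeR, with 387 and 320 at an unadjusted p under 0.05 and 184 and 91 by DESeq2 with the block. No low-count filter gave 575 higher, cells without Mki67 or Top2a 46 and 24, and cells matched on UMIs 86 and 33. Gating at 2000 UMIs gave 801 and 650, Izumo1r alone 427 lower, cells without the highest UMIs 155 and 84, and matched cells without the regulatory T-like cluster 73 and 36. Leaving out a mouse gave 153 to 303 higher and 85 to 149 lower.

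At 4000 UMIs Foxp3 was found in 21.7% of eye T cells, and without thinning in 30.9%. Izumo1r with Nt5e was found in 5.48% of Foxp3-negative cells at 1000 UMIs, 20.2% at 4000 and 33.2% without thinning, by construction. Of 17 shares, 13 moved by over 1 SD at 1000 UMIs, 14 at 4000 and 17 without thinning, and 0 under the other settings. The regulatory, Th17-like, cycling and naive T-like cluster shares moved by less than 1 SD under other clusterings. The macrophage or microglia-like share moved from 1.03% to 2.30% with 15 components. Classes absent from the clustering used appeared: follicular helper T-like in all 3 others (20.2% and 10.1% at resolutions 0.5 and 1.2, 16.04% with 15 components), Th1 effector T-like at resolution 1.2 (2.79%) and anergic T-like with 15 components (4.00%).

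With an estimated correlation the regulatory list had adjusted p = 0.278 in the eye comparison, 0.256 in the Foxp3 gate and 0.352 in the FR4 CD73 gate, and the anergy list 0.278 in the eye comparison. With that setting 20 of 29 lists lost their call in the eye comparison, 10 of 27 in the Foxp3 gate and 13 of 23 in the FR4 CD73 gate. These were all the lists that had passed. The setting also rests on 3 residual degrees of freedom, so the losses cannot be put down to correlation alone. With fry, the FR4 CD73 gate lost 7 of those 13 calls: regulatory, oxidative phosphorylation (0.0544 each), naive (0.116), interferon (0.131), Th1 and co-inhibitory (0.180 each) and cytotoxic genes (0.480). Calls were gained with fry by 6 lists in the eye comparison and 6 in the Foxp3 gate. Among them were follicular helper genes in the former (8.14e-04) and activation genes in the latter (0.00786). Unlike camera, fry asks whether a list's genes changed at all, not whether they changed more than other genes. Directions turned for lists that had not passed. In the Foxp3 gate these were cytotoxic genes with fry (0.0372) and with no replicate block (0.907), TGF-beta response with fry (0.503) and residency with fry (0.674). In the FR4 CD73 gate they were Th2 with fry (0.849), chemokine receptors with fry (0.849) and with no replicate block (0.967), and apoptosis without ribosomal and mitochondrial genes (0.995). The block changed no list call outside the 5 given for the FR4 CD73 gate.

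Foxp3 was at −9.76 in the eye comparison limited to eye cells with 0 Foxp3 UMI, by construction and as a fitted value that is no bound, and Mki67 at −0.0616 in the Foxp3 gate set at 2000 UMIs. In the FR4 CD73 gate set at 2000 UMIs, Hist1h3c was at −0.24, Hecw2 −0.28, Cenpf −0.41, Kif20b −0.11, Ccnb1 −0.56, Ccna2 −0.59, Ube2c −0.44, Cdca8 −0.42, Tpx2 −0.56, Clspn −0.56, Dtl −0.19, Mki67 −0.41, Top2a −0.48, Hmgb2 −0.44 and Il17a −0.80, with Dgka at 0.0608, Satb1 0.19, Cxcr6 0.18, Ifi206 0.41 and Junb 0.0676. With Izumo1r alone, Ms4a4b was at 0.63, Dgka 0.20, Satb1 0.36 and Klrd1 0.29, with Icos at −0.0304, Irf4 −0.0580, Ccl20 −0.18, Il21 −0.0479, Pdcd1 −0.30 and Il17a −0.79. Without cycling cells Ube2c was at −0.29 and Hmgb2 at −0.40. With matched cells Ccl3 was at −0.26, Clspn −0.34 and Top2a −0.0821. Without the regulatory T-like cluster Ccl3 was at −0.43 and Ccr2 at −0.0346, without the Foxp3-rich cycling cluster as well Ccr2 was at −0.55 and Ccr9 at −0.15, and with matching besides the first, Il7r was at 0.0357 and Clspn at −0.31.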

Other observations

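The test of Foxp3 by donor sex in this part was chosen before its result was seen, and the per-cluster values are descriptions without a test. FR4 and CD73 transcripts were spread differently over the eye clusters at 2000 UMIs. Izumo1r was found in 42.5% ± 10.2 of regulatory T-like cells (SD, n = 4) and in 8.66% ± 2.91 of Th17-like cells. Nt5e was found in 74.99% ± 3.36 and 68.0% ± 3.10 of these, and in 47.1% ± 1.33 of naive T-like cells of the eye. Lag3 was found in 66.6% ± 4.60 of regulatory T-like and 34.9% ± 5.36 of Th17-like cells, whereas Pdcd1 was in 15.9% ± 5.74 and 34.5% ± 9.001.

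Of the 2 cycling clusters, one had Foxp3 in 24.4% ± 8.73, Il10 in 20.9% ± 7.72, Izumo1r in 27.7% ± 6.01 and Il17a in 12.4% ± 6.60 of its cells. The other had Foxp3 in 1.34% ± 1.25, Il10 in 2.05% ± 1.48, Izumo1r in 10.5% ± 7.32 and Il17a in 37.3% ± 10.98. Nt5e was in 53.7% ± 7.26 and 45.3% ± 8.19 of these, and Mki67 in 79.3% and 80.3%. In the cluster led by Klrd1, Klrk1 and Gzma, Ifng was found in 11.99% ± 5.79 of cells and Il10 in 0.976%. Free RNA sets a floor for such shares that was read in 32 photoreceptor-like cells and, for Foxp3, Il10 and Ikzf2 only, in T cell clusters with low shares.

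A hypothesis was that cells of 1 sex turn on Foxp3 more often in the eye, since the transferred cells were of mixed sex and Foxp3 is X-linked. Xist-only cells had the higher Foxp3 share in 2 of 4 mice (9.68%, 23.2%, 9.35% and 16.1%, against 12.3%, 18.1%, 5.63% and 16.9% in Y-linked cells of mice 1 to 4). The mean difference was 1.34 points ± 3.65 (SD, two-sided exact sign-flip p = 0.5, where 4 mice allow 0.125 at the smallest). The data gave no common direction.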
